A study of Homo sapiens with 6 samples.

How the data were processed

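RNA of RPMI-8402 leukaemia cells carrying Cas9 was sequenced as strand-specific paired-end libraries, per the labels' protocols, in 3 DMSO and 3 doxycycline (DOX) samples at 72 hours. The authors deposited a table of raw read counts per Ensembl gene and a table of their own DOX against DMSO comparison. The tools STAR 2.5.2a, featureCounts and DESeq2 1.12.4 and the human build hg19 are named per the submitters' processing notes, with no order or role. The annotation release and the strand setting of the counting were not given in the sources used here, so reads of overlapping and antisense genes were not told apart with certainty. The authors' table gives, per the file headers, a mean of normalised signal over all libraries, a log2 fold change with its standard error, a test statistic (a score) and p-values. Its direction was checked against the counts and is DOX over DMSO. Series text names guides against MYC and MYCN, while the treatment text names MYC and the genotype label of the DOX samples names MYCN; both genes were treated as targets.

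The count columns show the group in their names but carry a number that is in no label, so a column was assigned to a group and not to a numbered replicate. No column of per-library values was left unused. The 92 spike-in rows held 0 counts in every library and were left out. Totals ran from 28602145 to 29204148 counts per library. No pair of libraries agreed within sampling noise: the mean chi-square per gene between libraries was at least 4.57, so all 6 were counted separately. Library-level precision is set by 3 libraries per group.

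Genes were filtered with edgeR's filterByExpr by group, scaled with TMM factors, and tested with edgeR 4.0.16 (robust quasi-likelihood F test, R 4.3.3), with the group as the only term and Benjamini-Hochberg adjustment over 15949 genes at a threshold of 0.05. The standard error printed beside an edgeR log2 fold change is its size divided by the square root of the F statistic. CPM are counts scaled by library total and TMM factor, computed here, and log2 CPM used a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives. Exact permutation tests of log2 CPM over all assignments of the 6 libraries into groups of 3 were two-sided.

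Before the data were examined, 37 gene lists were fixed, with 35 holding at least 3 tested members. Each was described by its median log2 fold change, by counts of called members over all genes and adjusted over the list alone, and by camera with a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the lists. Fry asks whether the genes of a list move, on balance, one way, and not whether they differ from other genes. The genes named were fixed by a rule: MYC, MYCN and their network; the 10 genes with the largest fold change in each direction among called genes with at least 10 CPM in the higher group, no overlap between groups, and a symbol that is not a clone name; and from each list up to 4 called members and 2 of the minority direction, or the 2 most expressed members where none was called. Because the main test called few genes, the same rule was also read on DESeq2's calls, which was decided after the data were seen, and genes with the smallest edgeR p were taken first.

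Chromosome, gene order, GC content and transcript length came from GENCODE 29, which was matched by Ensembl gene ID for 15462 of the genes tested, with GC content and length for 96.9%. This annotation is of another build than the authors', so no coordinates are printed.

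The tests were tried on simulated counts drawn from the means, dispersions and library sizes of this comparison, with 200 changed genes. The 57 MYC targets were also lowered 1.5-fold, and their calls are part of the totals below. Genes were drawn independently, with no shift shared across a library such as that of DMSO 11, so the recovery may not hold for the real libraries. EdgeR, on 15691 simulated genes, recovered 83.0% of the 2-fold changes and 44.0% of the 1.5-fold changes with 9 false calls of 169, DESeq2 on 15949 recovered 87.0% and 63.0% with 37 false calls of 232, and voom recovered 82.0% and 41.0%.

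Alternatives fixed before the data were seen were DESeq2, voom, other scalings (DESeq2 size factors, upper quartile, total count), no filter, a filter of at least 1 CPM in 3 libraries, a threshold of 0.01, a non-robust fit, each library left out in turn, other list tests, and a window of 10 Mb for the genes telomeric of the targets. Added after the data were seen were edgeR's likelihood ratio test, edgeR's newer dispersion method, voom with library quality weights, 1 surrogate variable (sva 3.50.0) and offsets for GC content and length. The replicate block by the labels' numbers could not be fitted, since the columns carry none of them; a block with pairs assumed from the order of the column numbers was added after the data were seen. Figures were drawn with matplotlib.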

Results

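RNA was measured by strand-specific sequencing in RPMI-8402 cells, a T-cell acute lymphoblastic leukaemia line that here carried Cas9 stably. Cells received the solvent DMSO or doxycycline, which switched on guide RNAs against MYC and MYCN, and were harvested after 72 hours. Each group held 3 libraries, which are named here by group and by the number in the count columns: DMSO 11, 23 and 35, and DOX 12, 24 and 36. The total counts were 29204148 in DMSO 11, 29062611 in DMSO 23, 28952786 in DMSO 35, 28602145 in DOX 12, 28911373 in DOX 24 and 28665963 in DOX 36. After a filter on low counts, 15949 genes were tested. The 37 rows of mitochondrially encoded genes held 0 counts in every library, so these genes were not measurable here. Nothing states that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No library of cells given doxycycline without guides was analysed here, so the response to the drug and the response to the guides were measured together.

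The first question was whether the targeted transcripts were lower. MYCN (ENSG00000134323, chromosome 2), a MYC family transcription factor, was lower in each DOX library than in each DMSO library, at 46.2 to 53.7 CPM (counts scaled by library total; lowest to highest library) against 91.1 ± 16.7 CPM (mean ± SD, n = 3 per group). Its log2 fold change was -0.87 ± 0.13 (SE). MYC (ENSG00000136997, chromosome 8), the proto-oncogene that drives growth and ribosome production, stood at 200 ± 6.57 CPM in DOX against 245 ± 39.7 CPM in DMSO, a log2 fold change of -0.30 ± 0.12, with overlapping groups. Neither gene passed the threshold of edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p-values of 0.0726 for MYCN and 0.176 for MYC. DESeq2's Wald test gave adjusted p-values of 7.92e-06 for MYCN, which it called, and 0.147 for MYC. Two-sided exact permutation tests gave p = 0.1 for MYCN, the smallest value that 3 libraries against 3 allow, and p = 0.2 for MYC. Without DMSO 11, MYCN passed the edgeR test with a log2 fold change of -0.98 and an adjusted p of 2.26e-07. MYC was at -0.20 with an adjusted p of 0.0566. That fit called 8109 of its 16412 genes. A gene count covers the whole transcript and reports neither the edit at the cut site nor the protein.

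**Figure D1:**
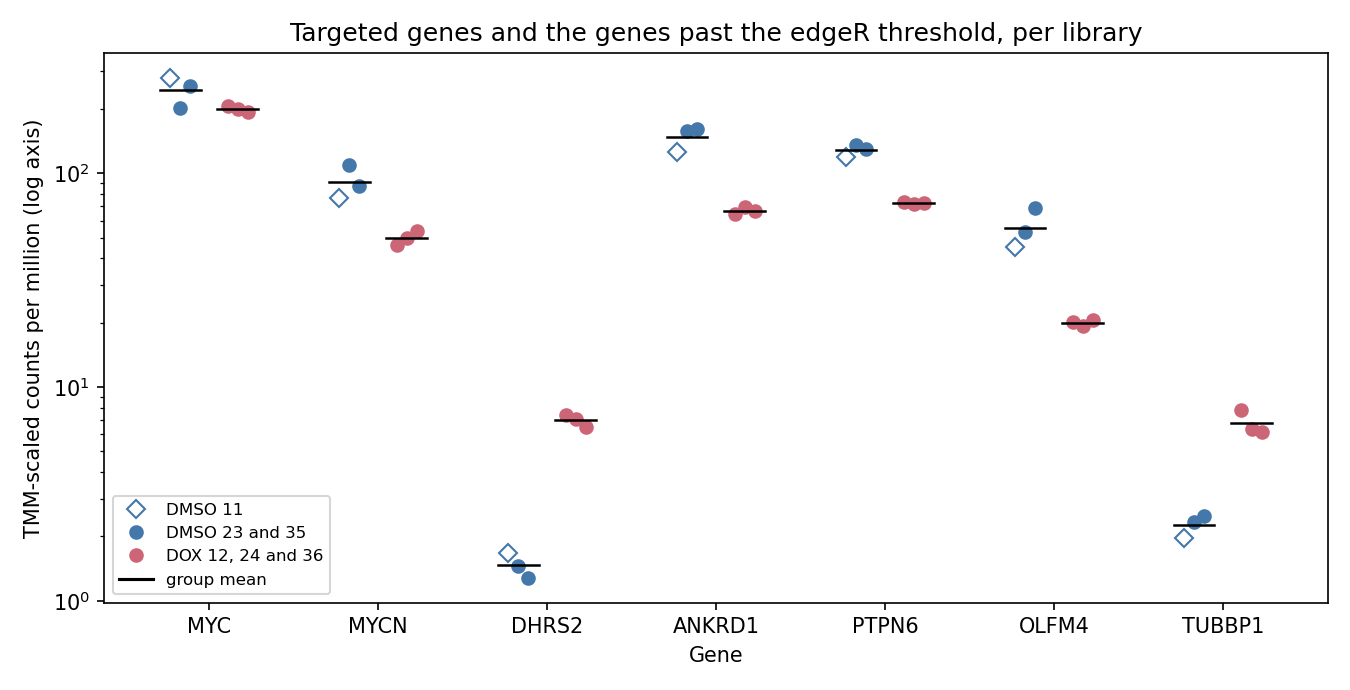
TMM-scaled CPM on a log axis for MYC, MYCN and the 5 genes past the edgeR threshold, with 1 point per library and a bar at each group mean (n = 3). DMSO 11 is the open diamond; the MYC groups overlap, and the groups of the other 6 genes do not.

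Across all genes, 5 passed edgeR's quasi-likelihood test at an adjusted p of 0.05. DHRS2, a mitochondrial and nuclear short-chain dehydrogenase, rose from 1.47 ± 0.198 CPM in DMSO by a log2 fold change of 2.25 ± 0.16 (adjusted p = 0.00687). The tubulin pseudogene TUBBP1 rose by 1.58 ± 0.17 on the log2 scale (adjusted p = 0.0324); its reads can be shared with tubulin genes of near-identical sequence, so its value is uncertain. ANKRD1, an ankyrin repeat co-regulator of transcription, fell from 148 ± 19.8 to 66.7 ± 2.43 CPM, with a log2 fold change of -1.15 ± 0.11. OLFM4, a secreted glycoprotein, fell from 55.6 ± 11.9 CPM in DMSO by a log2 fold change of -1.47 ± 0.15, and PTPN6, the phosphatase SHP-1 that dampens antigen receptor signals, fell from 128 ± 8.97 to 72.7 ± 0.634 CPM (-0.82 ± 0.08). The adjusted p was 0.0263 for each of these 3 genes. DHRS2 and TUBBP1 lie below the CPM minimum of the rule for named genes and were chosen after their values were seen. The count of calls rested on single libraries and on the test: edgeR called 8109 genes without DMSO 11, 3894 higher and 4215 lower in DOX, and 0 genes when any of the other 5 libraries was left out, with 2273 to 2629 genes at an unadjusted p under 0.05. DESeq2 called 1399 genes over all 6 libraries, 437 higher and 962 lower, and 4150 genes had an unadjusted edgeR p under 0.05.

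**Figure D2:**
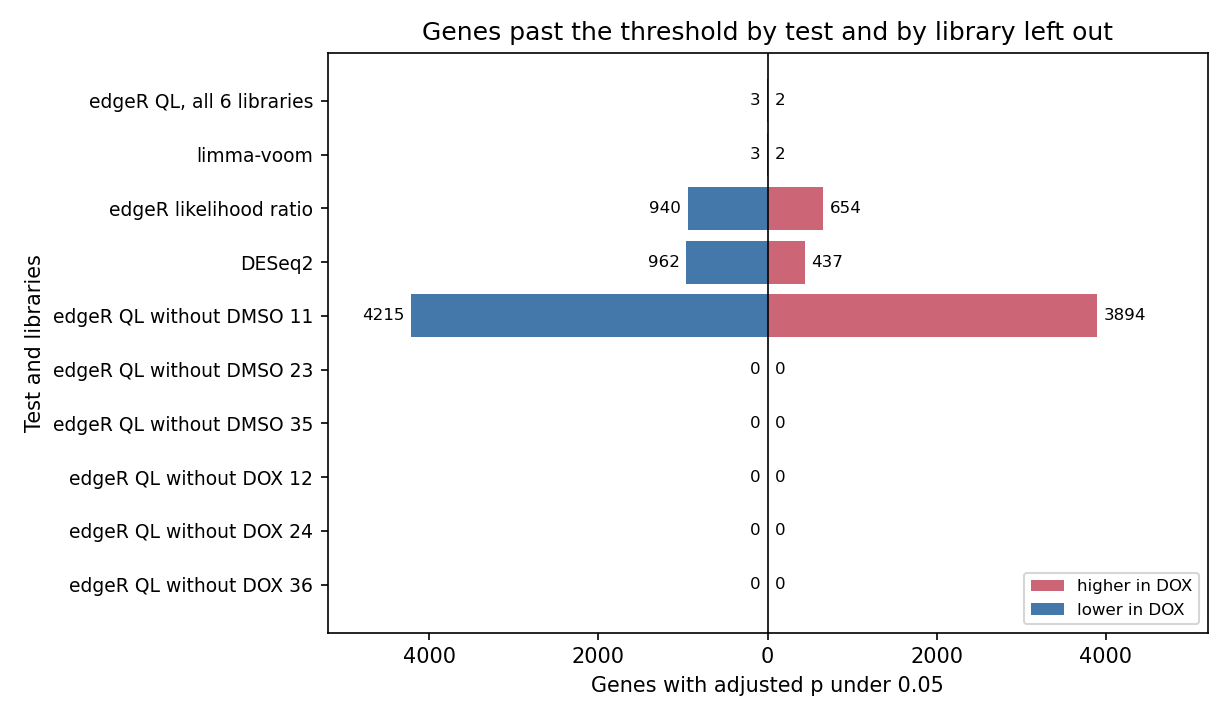
Number of genes with an adjusted p under 0.05, higher in DOX to the right and lower to the left, for 4 tests on all 6 libraries and for edgeR's quasi-likelihood test (QL) with each library left out. The quasi-likelihood test called 5 genes with all libraries and 8109 without DMSO 11.

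DMSO 11 stood apart from the other DMSO libraries. Its root mean square log2 distance over 9311 genes with a mean of at least 10 CPM was 0.43 to DMSO 23 and 0.41 to DMSO 35, against 0.18 to 0.21 to the 3 DOX libraries. The DOX libraries lay 0.11 apart from each other and DMSO 23 and DMSO 35 lay 0.17 apart. The first principal component, with 79.5% of the variance, set DMSO 23 and DMSO 35 against the other 4 libraries, and the second, with 10.7%, set DMSO 11 against the DOX libraries. In 4817 genes, 30.2% of those tested, the 3 DOX libraries lay above (2334) or below (2483) the 3 DMSO libraries, where an average over all splits of the 6 libraries gives 10%. The other splits gave 2.68% to 17.4%, and the highest set DMSO 11, DOX 12 and DOX 24 against the rest.

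**Figure D3:**
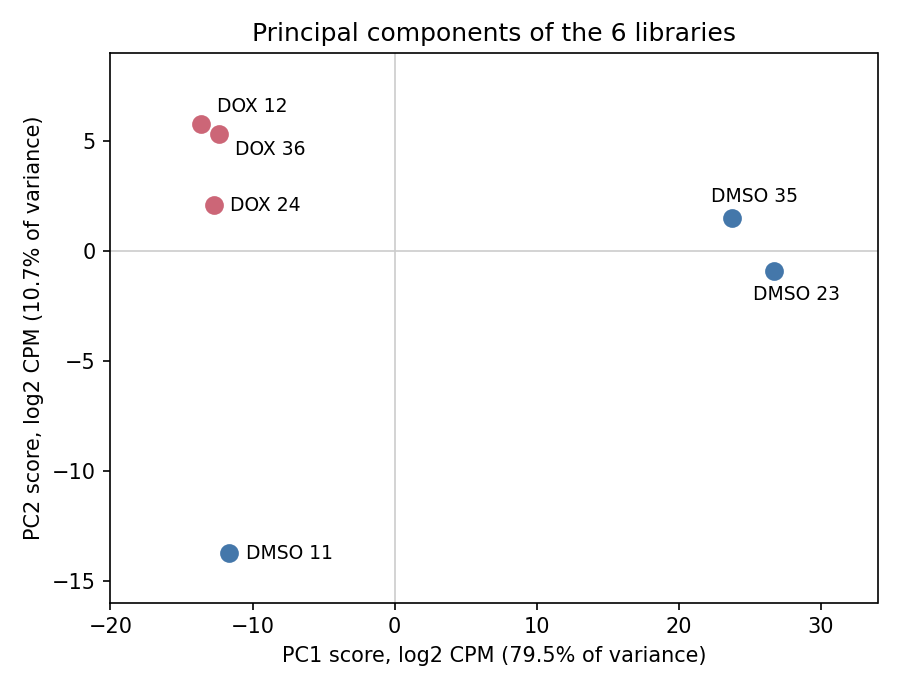
Scores of the 6 libraries on the first and second principal components of log2 CPM over 9311 genes. DMSO 11 has a PC1 score of -11.7, near the DOX libraries, and DMSO 23 and DMSO 35 have scores of 26.7 and 23.7.

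Among the genes that DESeq2 called, the fold changes listed next are from edgeR and the adjusted p-values from DESeq2. The rule for named genes was applied to these calls after the data were seen, because edgeR called few genes. TXNIP, an arrestin-like brake on glucose uptake, stood at 298 ± 144 CPM in DMSO and 66.9 ± 3.44 CPM in DOX (log2 fold change -2.15 ± 0.35, adjusted p = 0.000538), and its relative ARRDC4 was lower at -1.36 ± 0.38 (adjusted p = 0.00365). The glucose transporter SLC2A3 was higher at 1.24 ± 0.21 and the glycolytic aldolase ALDOC at 1.31 ± 0.15, with adjusted p-values of 2.25e-05 and 5.29e-10. TSC22D3, a glucocorticoid-induced leucine zipper protein, the linker histone H1F0 and the cholesterol exporter ABCA1 were lower in DOX by DESeq2, at -2.05 ± 0.50, -1.81 ± 0.48 and -1.61 ± 0.36 (DESeq2 adjusted p = 0.0262, 0.0453 and 0.0179). Other genes called lower were DAND5, an inhibitor of secreted growth factors, at -1.66 ± 0.24, and CCDC138 at -1.38 ± 0.32. The p53 target genes TP53INP1 and ZMAT3 were called higher, at 1.55 ± 0.27 and 1.15 ± 0.22, as were the receptor kinase FGFR1, from 31.5 ± 9.14 to 62.9 ± 2.53 CPM, and the adhesion molecule MCAM at 1.15 ± 0.28. For TXNIP, DMSO 11 held 132 CPM where DMSO 23 and DMSO 35 held 397 and 364, and for TSC22D3 it held 45.5 CPM against 238 and 207. For H1F0 it held 121.9 CPM against 626 and 435, with 121.6 in DOX 36. For ABCA1 it held 19.6 CPM against 59.5 and 58.4, with 16.6 in DOX 36. ARRDC4 stood at 5.43 CPM in DMSO 11 against 16.3 and 17.9, with 5.32 in DOX 36. CCDC138 stood there at 89.5 CPM against 245 and 237, with 75.5 in DOX 24. MCAM was at 13.0 CPM in DMSO 11 against 6.33 and 5.61, with 17.8 in DOX 24. In the other genes named here, DMSO 11 was likewise the DMSO library nearest the DOX libraries. The edgeR adjusted p-values over the genes named in this group ran from 0.0504 for ALDOC to 0.101 for ARRDC4.

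MYC and MYCN drive ribosome production and nucleotide supply, so lists of these genes were fixed in advance. For scale, DESeq2 called 437 higher (31.2% of its calls) and 962 lower of the 13653 genes with an adjusted p. Of 57 tested MYC targets, edgeR called 0 over all genes, DESeq2 called 1 higher and 9 lower, and the median log2 fold change was -0.09. The lower ones included EXOSC5, a subunit of the RNA exosome, at -0.94 ± 0.19, WDR74 at -0.59 ± 0.12 and the arginine methyltransferase PRMT3 at -0.50 ± 0.10, and the higher one was the hexokinase HK2 at 0.52 ± 0.10. Of 65 ribosome biogenesis genes, DESeq2 called 6 lower and 0 higher, among them UTP18 at -0.57 ± 0.11 and the rRNA methyltransferase EMG1 at -0.55 ± 0.11, and the median was -0.11. Of 27 nucleotide synthesis genes it called 4 lower and 0 higher, among them the purine enzymes ATIC at -0.50 ± 0.09 and GART at -0.30 ± 0.08, and the median was -0.10. Adjusted over the list alone, edgeR counted 9 MYC targets, 2 ribosome biogenesis genes and 5 nucleotide synthesis genes as lower, and 1 MYC target as higher. With a preset correlation of 0.01, camera gave adjusted p-values of 0.110, 0.0152 and 0.0312 for the 3 lists, and with an estimated correlation the adjusted p-values were 0.880, 0.717 and 0.716. Without DMSO 11, in which these lists were highest, the medians of the MYC targets, the ribosome biogenesis genes and the nucleotide synthesis genes were 0.01, -0.07 and 0.02, and camera's preset calls of ribosome biogenesis and nucleotide synthesis ended (adjusted p = 0.648 and 0.605). They also ended without DOX 36 (0.0837 and 0.114), as did nucleotide synthesis without DOX 12 (0.0676), while the MYC targets passed without DMSO 23 (median -0.14, adjusted p = 0.00129) or DMSO 35 (0.00924). The nucleotide synthesis median was -0.16 without DMSO 23 and -0.17 without DMSO 35.

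Genes of the MYC dimerization network differed in direction among the DESeq2 calls. MAX, the obligate partner, stood at 116 ± 18.8 CPM in DMSO and 88.4 ± 3.37 CPM in DOX (log2 fold change -0.40 ± 0.12, DESeq2 adjusted p = 0.0432). The antagonist MXI1 was lower at -0.59 ± 0.14 and the antagonist MXD4 higher at 0.93 ± 0.18 (DESeq2 adjusted p = 0.00889 and 0.000633). None of the 11 tested network genes passed edgeR's test over all genes. Each of these 3 genes passed it without DMSO 11, in a fit where 8109 of 16412 genes passed.

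Genes downstream of NOTCH1, the receptor whose activation is a hallmark of this leukaemia, gave a mixed result by test. Of 20 tested NOTCH targets, DESeq2 called 8 lower and 0 higher, and edgeR, adjusted over the list alone, counted 11 lower, against 0 over all genes. The complement receptor CR2 stood at 264 ± 47.0 CPM in DMSO and 144 ± 4.08 CPM in DOX (log2 fold change -0.88 ± 0.13), SHQ1 was at -0.53 ± 0.09, the pre-T-cell receptor chain PTCRA at -0.73 ± 0.16 and the repressor HES1 at -0.33 ± 0.08. The list's median was -0.33 and its camera adjusted p was 0.000936 with the preset correlation, and adjusted p = 0.716 with an estimated correlation. In 10 of the genes all DOX libraries lay below all DMSO libraries, and in 3 above. The median deviation was 0.35 in DMSO 23 and 0.19 in DMSO 35, against -0.05 in DMSO 11, and the DOX mean was lower by 0.10 than DMSO 11 and by 0.37 than the mean of the other 2 DMSO libraries. The median fold change was -0.38 without DMSO 11 and -0.22 without DMSO 23.

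Stress response and tRNA charging genes were highest in DMSO 23 and DMSO 35, and lower in DOX and in DMSO 11. The median log2 fold change was -0.52 over 29 integrated stress response genes, the program of the transcription factor ATF4, -0.28 over 19 aminoacyl tRNA synthetases and -0.44 over 15 snoRNA and lncRNA host genes. DESeq2 called 4, 3 and 2 of them lower and 0 higher, edgeR 0 over all genes, and edgeR adjusted over the list alone counted 2, 0 and 4 as lower. ATF3 was at -0.56 ± 0.10 and CHAC1, which degrades glutathione, at -0.60 ± 0.14, the tyrosyl tRNA synthetase YARS at -0.60 ± 0.17, and the snoRNA host SNHG15 at -0.65 ± 0.19. Camera's adjusted p-values were 0.000936, 0.00153 and 0.0196 with the preset correlation, and each was 0.716 with an estimated correlation. For the stress response list, the median deviation from the mean of all libraries was 0.47 in DMSO 23 and 0.39 in DMSO 35, against -0.21 in DMSO 11 and -0.25 to -0.15 in the DOX libraries. Against DMSO 11 alone, the DOX mean was higher by 0.16 for the stress response list and by 0.09 for the snoRNA hosts, and lower by 0.08 for the tRNA synthetases. The stress response median was -0.28 without DMSO 23. The snoRNA host median was -0.75 without DMSO 11, and its preset call ended without DMSO 23 (median -0.16, adjusted p = 0.143) and without DMSO 35 (adjusted p = 0.0612).

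**Figure D4:**
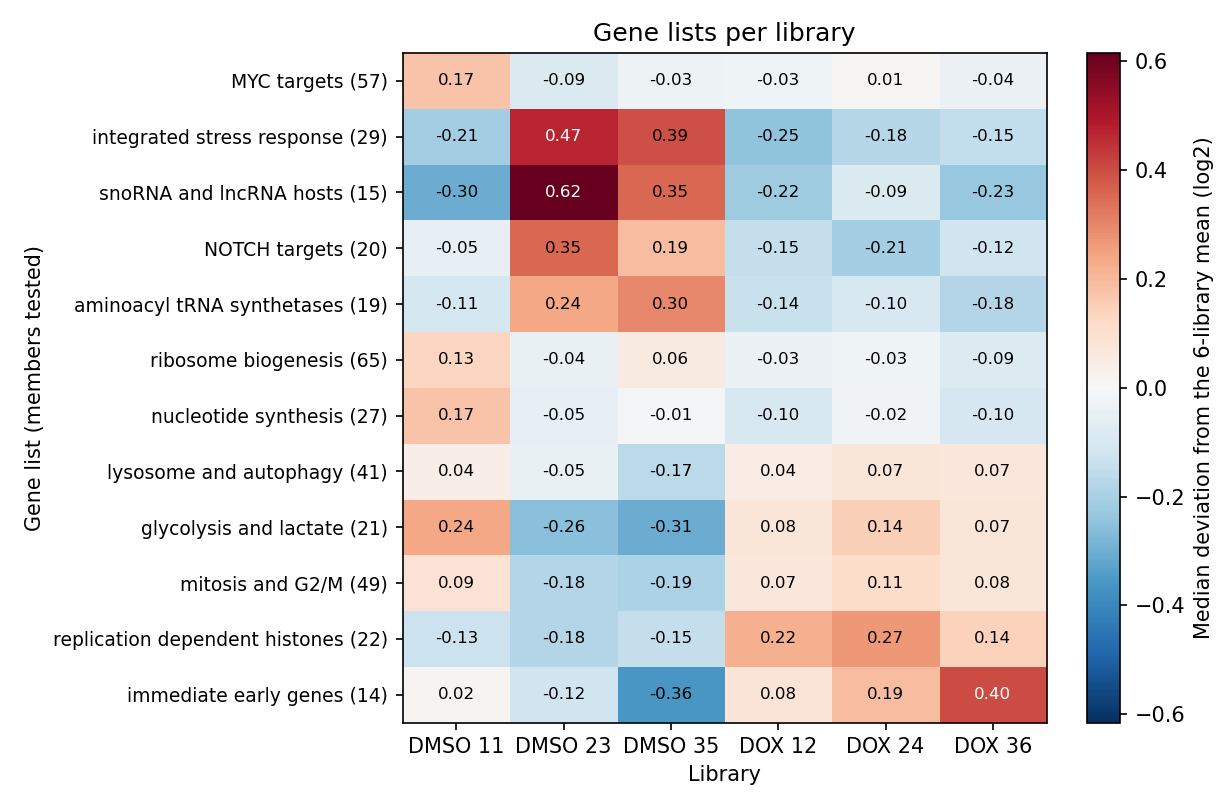
Median deviation of each gene list from its mean over the 6 libraries (log2 CPM), per library, for the MYC targets and the 11 lists past camera's threshold with the preset correlation, with the number of members tested. DMSO 11 has the stress response at -0.21 and the MYC targets at 0.17, where DMSO 23 has 0.47 and -0.09.

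Glycolysis, mitosis, lysosome, histone and immediate early genes passed camera's test as higher in DOX with the preset correlation, and none of these 5 lists passed with an estimated correlation (adjusted p = 0.716 for each). The medians were 0.18 over 21 glycolysis and lactate genes, 0.19 over 49 mitosis and G2/M genes, 0.11 over 41 lysosome and autophagy genes, 0.34 over 22 replication dependent histones and 0.54 over 14 immediate early genes. DESeq2 called 4 glycolysis genes higher and 0 lower, including the lactate transporter SLC16A1 at 0.37 ± 0.10, while GAPDH (0.13 ± 0.15) and ENO1 (0.11 ± 0.15) were not called. Without DMSO 11 edgeR called both, at 0.31 and 0.30 (adjusted p = 0.00333 and 0.00302), in a fit that called 8109 of 16412 genes. Their lowest values with 1 library left out were 0.04 and 0.02. DESeq2 called 3 mitosis genes higher, among them the proliferation marker MKI67 at 0.61 ± 0.18 and the topoisomerase TOP2A at 0.40 ± 0.12. It called 2 lower, HMMR at -0.45 ± 0.09 and NDC80 at -0.54 ± 0.16, whose groups overlapped (69.3 CPM in DMSO 11, 69.8 in DOX 24). It called 6 lysosome and autophagy genes higher, such as the peptidase TPP1 at 0.60 ± 0.12 and the autophagy kinase ULK1 at 0.53 ± 0.15, 2 histones, HIST1H4H at 1.53 ± 0.23 and HIST1H3H at 1.11 ± 0.29, and 3 immediate early genes, JUN at 0.79 ± 0.21, EGR1, from 1.07 ± 0.610 to 2.31 ± 0.410 CPM, and IER3 at 1.01 ± 0.18. Histone genes share sequence, and both named histones had a mean below 2 CPM in each group. Adjusted over the list alone, edgeR counted 4, 0, 2, 5 and 5 genes higher and 0, 0, 0, 0 and 1 lower in these 5 lists, and over all genes 0 in each. The camera adjusted p-values were 0.000795, 0.000936, 0.00202, 0.000936 and 0.0152 with the preset correlation. Against DMSO 11 alone, the DOX mean was lower by 0.12 for glycolysis and higher by 0.00410 for mitosis, 0.04 for the lysosome, 0.41 for the histones and 0.27 for the immediate early genes. Without DMSO 11 the medians of glycolysis, mitosis and lysosome genes were 0.39, 0.29 and 0.17. Camera's preset calls of the histones and the immediate early genes ended in that fit, with adjusted p-values of 0.139 and 0.123. Their medians, over the members tested with all libraries, were nevertheless higher than in the main fit, at 0.43 and 0.72. Camera sets a list against all other genes, of which many more passed in that fit. It also covered every member tested in that fit, a set that can differ from that of the medians. The ended calls therefore do not show a smaller shift. The glycolysis median was 0.10 without DMSO 23 and 0.09 without DMSO 35. The lysosome median was 0.05 without DMSO 35, the immediate early median 0.35 without DMSO 35, and the call of the immediate early genes ended without DOX 36 (adjusted p = 0.0727).

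In cell death, p53 and lymphoid lists, named members went both ways. Of 25 p53 targets, DESeq2 called 3 higher, including the death effector BAX at 0.38 ± 0.10, and 1 lower, GADD45A at -1.05 ± 0.17. The survival gene BCL2 was higher at 0.57 ± 0.10 and the BH3-only gene PMAIP1 lower at -0.39 ± 0.11, the 2 calls among 21 apoptosis regulators. Among 38 T cell genes, DESeq2 called 4 higher, with the chemokine receptor CCR9 at 0.81 ± 0.23, and 3 lower, with the transcription factor LEF1 at -0.48 ± 0.14 and the egress receptor S1PR1 at -0.81 ± 0.20. Of 42 interferon response genes it called 3 lower, with IRF1 at -0.73 ± 0.09 and IFITM1 at -0.54 ± 0.09, and 1 higher, SAMD9 at 0.57 ± 0.17. The oncogene LMO1 was lower at -0.36 ± 0.07, with 157 ± 2.91 CPM in DMSO and 123 ± 3.34 CPM in DOX. EdgeR called 0 members of these lists over all genes, and camera's preset adjusted p was 0.457 for the p53 targets, 0.902 for the apoptosis regulators, 0.408 for the T cell genes and 0.902 for the interferon genes.

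The authors' deposited table of the same contrast held 1362 genes with an adjusted p under 0.05, 421 higher and 941 lower in DOX, of 14237 genes with a value. DESeq2 run here on the counts shared 1353 of these calls, and all 5 genes called by edgeR were among them. Every one of the 1362 had the same sign in the edgeR fit, and in 1258 of them the groups did not overlap. Both fits used the same libraries and the genes were selected by a small p, so neither count is independent support. The authors' deposited table gave MYCN a log2 fold change of -0.87 with an adjusted p of 8.26e-06, and MYC -0.30 with 0.151.

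A Cas9 cut can remove the chromosome end beyond it, so genes between each target and the telomere were compared with the rest of the chromosome. The 61 tested genes telomeric of MYCN on chromosome 2 had a median log2 fold change of 0.14, against -0.02 for the other 936. It was 0.02 over the 38 genes within 10 Mb. With 1 library left out it was 0.07 to 0.11, over the genes tested in each fit, which can differ from these 61. The 99 genes telomeric of MYC on chromosome 8 had a median of 0.04, against -0.04 for the other 443. Neither set passed camera's test with the preset correlation (p = 0.298 and 0.189, unadjusted).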

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

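The alternatives with the likelihood ratio test, the newer dispersion method, library quality weights, 1 surrogate variable, GC content and length offsets and an assumed replicate block were chosen after the data were seen. Of 15 alternatives on all libraries, 8 kept each count of genes within 1.5 times. Genes higher, genes lower, and those at 2-fold or more in each direction were 437, 962, 70 and 133 with DESeq2, 615, 1146, 161 and 170 with no filter on low counts, 1, 0, 1 and 0 at a threshold of 0.01, 654, 940, 181 and 172 with the likelihood ratio test, 3403, 3684, 479 and 436 with quality weights, and 2156, 2213, 258 and 81 with 1 surrogate variable. The authors' deposited table shared 1353, 1093, 1, 1266, 1362 and 1358 calls with these, in the same order. Without 1 library each, the counts ran from 0 to 3894, 0 to 4215, 0 to 590 and 0 to 598, and the shared calls from 0 to 1361, with every upper end from the fit without DMSO 11. The cause was not tested.

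MYCN stayed lower throughout and passed the threshold with DESeq2 (-0.87), no filter (-0.88), the likelihood ratio test (-0.87), quality weights (-0.92) and 1 surrogate variable (-0.77), and ran from -0.98 to -0.72 with 1 library left out, passing only without DMSO 11; its adjusted p ran from 2.78e-09 to 0.0900 over the alternatives on all libraries. MYC stayed lower throughout, from -0.42 without DMSO 23 to -0.20 without DMSO 11, and passed with quality weights (-0.23) and 1 surrogate variable (-0.36) and in no other of the 15, where its adjusted p ran up to 0.214. The cause was not tested. Of the 11 gene lists past camera's threshold, 7 passed at 0.01. Quality weights kept 7 of them, and the filter of at least 1 CPM and the GC content and length offsets kept 9 each. The call of the immediate early genes ended in 5 of 17 alternatives on all libraries, other list tests included. Over these alternatives the stress response median ran from -0.64 to -0.19 and the snoRNA host median from -0.63 to -0.15. With an estimated correlation 0 lists passed, and with fry 2 lists did, the histones and the stromal and epithelial markers. The median of the genes telomeric of MYC was -0.00198 with GC content and length offsets. It ran from 0.00650 to 0.0946 with 1 library left out, with an unadjusted camera p under 0.05 only without DMSO 23. That of the genes telomeric of MYCN ran from 0.0657 to 0.105 with 1 library left out and was 0.0178 within 10 Mb. Each fit with 1 library left out used the telomeric genes tested in it. Without 1 library each, the median ran from -0.135 to 0.0115 for the MYC targets and from -0.168 to 0.0175 for nucleotide synthesis, above 0 only without DMSO 11. Over the 17 alternatives on all libraries, the MYC target median ran from -0.111 to -0.000447, and that list newly passed in 3. The nucleotide synthesis median ran from -0.166 to -0.0125, and its call ended in 7. The 70 genes named kept their sign in all 1470 other values, of which 367 newly passed and 31 no longer passed the threshold. Most of them were named for their values in these same counts, so a kept sign was likely from the start. Only the 5 genes called in the main fit could lose the threshold, and all 5 lost it when any library other than DMSO 11 was left out. No scaling moved the median of all genes by over 0.1. The count columns carry no replicate number of the labels, so pairs were assumed from the order of the column numbers (11 and 12, 23 and 24, 35 and 36). Deviations from the group means correlated at 0.0484, 0.0466 and 0.0714 within these pairs, none over 0.1, and no DMSO library correlated highest with its assumed partner, so the pairing is not supported. With this replicate block, 1 gene was higher and 2 lower, 1 and 2 of them at 2-fold or more, and 3 were shared with the authors' table; 3982 genes had an unadjusted p under 0.05. MYCN was at -0.85 and MYC at -0.28, and 10 lists passed. Total counts ran from 28602145 to 29204148, and depth limits statements on genes removed by the filter on low counts, which were not tested.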

Other observations

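Antigen receptor V segments, a set chosen after the data were seen, had lower medians in DOX at all 4 loci looked at. Of 50 tested immunoglobulin heavy chain V segments, 22 had all DOX libraries below all DMSO libraries and 0 had them above, with a median log2 fold change of -0.48. Of 11 T cell receptor beta V segments, 9 were separated in this way and 0 the other way, with a median of -1.21, and TRBV19 stood at 38.2 CPM in DMSO 11, 102 in DMSO 23 and 100.4 in DMSO 35, against 30.3 ± 0.988 CPM in DOX. Of all 15949 tested genes, 2483 were separated as lower and 2334 as higher. The alpha and gamma chain loci, with 4 and 9 tested segments, had medians of -0.79 and -0.34. Their camera adjusted p-values were 0.127 and 0.0624 with the preset correlation, and 0.262 and 0.353 with an estimated correlation. In the alpha chain 2 segments were separated as lower and 1 as higher, and in the gamma chain 1 and 0. Camera's adjusted p over the 4 loci was 1.04e-09 for the heavy chain and 6.75e-10 for the beta chain with the preset correlation, and adjusted p = 0.0798 for both with an estimated correlation. V segments resemble each other in sequence, so reads may be shared between them, and edgeR called 0 of them over all genes. Without DMSO 11 the medians were -0.55 for the heavy chain, -1.38 for the beta chain, -0.83 for the alpha chain and -0.56 for the gamma chain.

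Among the lists that did not pass camera's preset test, the heat shock and proteostasis genes had a median of 0.12 over 22 genes, with HSPA1B at 1.05 ± 0.32, and DESeq2 called 1 of them higher and 2 lower. By library, the median deviation of this list was 0.26 in DMSO 11, -0.25 in DMSO 23, -0.27 in DMSO 35 and 0.09 to 0.12 in the DOX libraries. Without DMSO 11 its median was 0.38, with 13 genes called higher and 4 lower and a camera adjusted p of 9.73e-10 with the preset correlation, and HSPA1B was at 1.60. The estimated correlation of this list over all libraries was 0.528, with an adjusted p of 0.910, and camera with an estimated correlation was not run without DMSO 11. The nuclear OXPHOS subunits and the CDK inhibitors and quiescence genes also passed with the preset correlation without DMSO 11, and not with all libraries. Camera's adjusted p-values were 0.000506 and 0.0297 in that fit, and 0.921 and 0.910 with an estimated correlation over all libraries. Of 75 OXPHOS genes, edgeR called 25 higher and 2 lower in that fit. Of all 16412 genes it called 3894 higher and 4215 lower there. DNA replication and G1/S genes had a median of 0.06 over 46 genes, and DESeq2 called 3 lower, among them the primase subunit PRIM1 at -0.60 ± 0.11 and the licensing factor CDT1 at -0.36 ± 0.10. Without DMSO 11 the median of these genes was 0.12, with 17 called higher and 9 lower by edgeR and a camera adjusted p of 0.0633. Cytosolic ribosomal proteins had a median of -0.08 over 78 genes, of which DESeq2 called 0. Of the B cell, myeloid and stromal marker lists, with 9, 4 and 4 tested genes, DESeq2 called 1, 0 and 1 genes, and camera's preset adjusted p-values were 0.549, 0.157 and 0.156.

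The tests in this part of label exchange, of MYCN in DMSO 11, of hypoxia genes and of other splits of the libraries were chosen only after the result was seen, and the held-out ATF4 targets were listed after the stress response list had been seen to differ. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 5 genes by edgeR, where the highest of the other splits gave 0, and it was the 1 split with as many. By DESeq2 it gave 1399 genes, where the highest other split gave 2 and 1 split gave as many. By camera with the preset correlation it gave 11 lists, where the highest other split gave 13 and 5 of the 10 splits gave as many, so the preset list calls do not single out the real split.

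DMSO 11 differed from DMSO 23 and DMSO 35 across the genome. GC content and transcript length explained 4.61% of the variance of that difference across genes, far too little for a whole cause. Its distance to the nearest DOX library was 1.61 times the largest distance among DOX libraries. At 0.18 it was near the 0.17 between DMSO 23 and DMSO 35, so it does not decide on an exchange of labels. Such an exchange is argued against by no DOX library lying out of place. All DOX libraries lay 0.39 to 0.44 from DMSO 23 and DMSO 35. A DOX library under a DMSO label is argued against by MYCN, which in DMSO 11 was 0.52 (log2 CPM) above the highest DOX library. The DOX libraries spanned 0.22 in MYCN. A library from outside the 6 or cells in which the guides had little effect stay open. Of ATF4 targets held out of the fixed lists, 6 of 6 tested were higher in the mean of DMSO 23 and DMSO 35 than in DMSO 11, by a median of 0.80 (log2), above all 10000 random lists matched on expression; these genes share their regulator with the list that prompted the test and random lists ignore such co-regulation, so this restates the pattern, and an amino acid stress state as its cause stays open. The labels give no culture density or medium age, so no biological explanation from the design was tested.

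MYCN was lower in DOX while MYC overlapped between groups. Loss of the chromosome end beyond the MYCN cut predicts lower neighbours, but genes telomeric of MYCN had a median log2 fold change higher by 0.16 than the other genes of the chromosome (bootstrap 95% interval -0.00 to 0.22), against -0.87 for MYCN itself. The bootstrap resampled genes as if independent and held the libraries fixed, so its interval does not measure the spread between libraries. The difference was 0.04 within 10 Mb. The median of the telomeric genes tested in each fit with 1 library left out stayed above 0, at 0.07 to 0.11. Decay of edited transcripts and lower transcription stay open, since gene counts do not tell them apart.

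ALDOC, SLC2A3, PPFIA4 and BNIP3, which are all known to respond to low oxygen, were higher in DOX with edgeR log2 fold changes of 1.31 ± 0.15, 1.24 ± 0.21 and 1.48 ± 0.22, and BNIP3 from 1.99 ± 0.288 to 4.57 ± 0.447 CPM (DESeq2 called each). PPFIA4 was chosen after its value was seen. A hypoxia response is a candidate explanation: 12 of 19 held-out hypoxia genes had a fold change above 0, with a median of 0.20, above 99.5% of 10000 matched random lists, which ignore co-regulation, and above 0 against each DMSO library, the lowest median being 0.09. The size fell short of the bound set for it, and members ran from -0.60 to 1.16, so whether this response raised the 4 genes stays open. For ALDOC and SLC2A3, a narrower change in sugar metabolism cannot be told apart from it.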
